A study of Mus musculus with 2 samples.

How the data were processed

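The series holds 2 samples from subcutaneous mouse tumours, 1 from animals on a control diet and 1 from animals on a serine/glycine-free diet, each with a gene expression library and a T cell receptor (TCR) library made with the 10x Genomics immune profiling assay, per the labels. The labels give no number of mice per library. Their extraction text describes human heart tissue, while the organism, source and design fields name mouse tumours; the gene symbols in the deposited matrices are mouse symbols. Per the file headers, the deposited count matrices hold UMI counts per gene and cell made with Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 2.2.2; the genome build per those notes is mm10. The deposited contig tables hold UMI and read counts per assembled contig, and every listed contig is marked as productive, full-length and of high confidence. Only barcodes called cells by the authors are in the matrices, so empty droplets were not analysed here and free RNA was judged from cell classes that should lack a gene. The control matrix holds 161332426 UMIs and the serine/glycine-free matrix 157234945.

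Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, which retained 8262 (97.6%) control and 7913 (98.9%) serine/glycine-free barcodes. Doublets were sought per library with the Scrublet method in scanpy 1.11.5. Its automatic thresholds of 0.601 and 0.595 marked 2 and 0 cells, so the doublet call did not work, and most doublets remain among the 8260 and 7913 analysed cells. Leaving out the 159 and 145 cells with a score over 0.25 was added as an alternative after the data were seen. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes (without TCR, immunoglobulin, mitochondrial, ribosomal, haemoglobin and sex-linked genes) gave 30 principal components, and both libraries were clustered together with 15 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 1). T-like clusters were clustered again in the same way. Clusters were named from marker lists fixed in advance; the numeric thresholds of the naming rule were set after the data were seen. A cluster needed at least 3 markers of a class in 20% or more of its cells and a mean log2 fold of 1.5 or more. A macrophage-type cluster with Krt20 in at least 50% of cells was called mixed and kept apart (100 and 108 cells, mean doublet score 0.310). A cluster whose leading genes held more markers of another class stayed unnamed, which left 94 control and 79 serine/glycine-free immune cells without a name. No cluster could be named as tumour cells, so the clusters with Ptprc in under 10% of cells and no other name were used as unnamed non-immune cells, as planned for that case.

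Barcodes of the contig tables were joined to the matrix of the same sample. A clonotype was an identical set of productive TRA and TRB CDR3 nucleotide sequences with their V and J genes, counted on T-like cells with at least 1 of each chain, and a clonotype of at least 2 cells was called expanded. Equal numbers of cells were drawn 1000 times. Shares have exact Clopper-Pearson 95% intervals, ratios of shares and of counts have intervals from the exact conditional binomial, and a count of 0 is given with the share that 3 counts would make. For TRBV genes the 3 most used per library and the 3 largest differences each way were named, counted by clonotype.

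For expression, UMIs were summed per library and class and divided by the total, without TCR and immunoglobulin genes, to give CPM (counts scaled to a common total) with exact Poisson intervals. Log2 ratios were taken of CPM plus 5. Named genes follow a rule fixed in advance: among genes with a mean of at least 50 CPM and a count of at least 30 in 1 library or more, the 10 with the highest and the 10 with the lowest log2 ratio per comparison (8 and 8 in unnamed non-immune cells), up to 4 genes of each described functional list, and a fixed set of immune genes. Functional lists were also fixed in advance, and their members with a mean of at least 20 CPM were measured. A list was described where its median log2 ratio lay under percentile 2.5 or over percentile 97.5 of 10000 random lists matched on size and on 25 expression bins, or where the design named it. Such a percentile describes these libraries only and says nothing on other mice. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. With 1 library per group no test between diets, no standard error and no count of changed genes is given. Cells of conventional dendritic 1, neutrophil, endothelial (22 and 16 cells) and other small classes were used for shares and for Cd274 and Pdcd1 only, because their sums were small; later checks of single gene groups used them as well.

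The expression steps were tested on simulated data: Poisson counts with the depth of each library and class, in which chosen genes of the joint mean profile were given a known ratio. In each of the 4 expression comparisons 100 of 100 genes planted at 2-fold had the right direction, with median log2 sizes of 1.00, 0.95, 0.97 and 0.96, and of 100 null lists 3, 4, 4 and 2 lay outside the percentile limits. Alternatives covered the cell filter, doublets, resolution, separate clustering, the clonotype definition, contig support, scaling (TMM from edgeR 4.0.16 in R 4.3.3, and median-of-ratios size factors), the pseudocount, the filter on low values and the weight of cells; the closing section gives their effect. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene positions come from the RefSeq annotation of GRCm38.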

Results

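Single-cell gene expression and T cell receptor sequences were measured with the 10x Genomics immune profiling assay in subcutaneous tumours of mice fed a control diet or a diet without serine and glycine. Each diet had 1 library, so there was no replicate check: both values are given with exact intervals that cover counting error only, and no test between diets was made. The control library held 8466 cell barcodes and 161332426 UMIs, with a median of 17540 UMIs per barcode. The serine/glycine-free library held 7999 barcodes and 157234945 UMIs, with a median of 16770. After filtering, 8260 and 7913 cells were analysed. Receptor contigs were listed for 256 control and 247 serine/glycine-free barcodes, all of which were in the count matrix of the same library. Every cell class below is named from marker genes and carries "-like" for that reason.

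The first comparison asked which immune cells the tumours held. Natural killer (NK)-like cells, which express Ncr1 and granzymes, made up 2.01% of cells (95% Clopper-Pearson interval 1.71 to 2.34) in the serine/glycine-free library and 0.508% (0.367 to 0.687) in the control library, a ratio of 3.95 (2.80 to 5.69; 159 and 42 cells). Monocyte-like cells were at 2.33% (2.0 to 2.68) against 4.56% (4.12 to 5.04), a ratio of 0.509 (0.425 to 0.609). Their cluster is led by Ly6c2 and Il1b but also by the MHC class II genes H2-Aa, H2-Ab1, Cd74 and H2-Eb1, so dendritic cells were not ruled out in it. T-like cells were at 2.81% (2.45 to 3.19) and 2.62% (2.28 to 2.98), with a ratio of 1.07 (0.886 to 1.30). All immune cells together formed 17.5% (16.7 to 18.3) of the serine/glycine-free library and 18.5% (17.7 to 19.4) of the control library. Among immune cells, NK-like cells made up 11.5% and 2.75%, and monocyte-like cells 13.3% and 24.7%, in that order.

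Macrophage-like cells, the most frequent immune class, formed 6.72% and 7.37% of the serine/glycine-free and the control library, a ratio of 0.912 (0.810 to 1.03). Neutrophil-like cells were at 0.682% and 0.630%. Conventional dendritic 1-like cells, which cross-present antigen to CD8 T cells, had a ratio of 1.23 (0.786 to 1.94). It was 2.09 without doublet removal and 1.96 without cells of a doublet score over 0.25. The former setting put back only 2 control cells, so its value reflects unstable cluster labels of this class and not doublets. Fibroblast-like cells were at 0.682% and 1.61%, a ratio of 0.424 (0.303 to 0.586). That ratio became 1.24 at a clustering resolution of 2.0 and 5.44 with each library clustered alone, because a cluster led by Mmp3 and Lum then carried the fibroblast name; thresholds set after the data were seen kept this cluster (693 control and 754 serine/glycine-free cells) among the unnamed non-immune cells. The unnamed non-immune cells formed 81.6% and 79.6% of cells, and no marker list separated tumour cells among them. The NK-like ratio was 5.99 under a stricter cell filter, and the T-like ratio was 9.96 at a resolution of 0.5, where most control T-like cells joined an unnamed cluster led by granzyme genes.

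**Figure D1:**
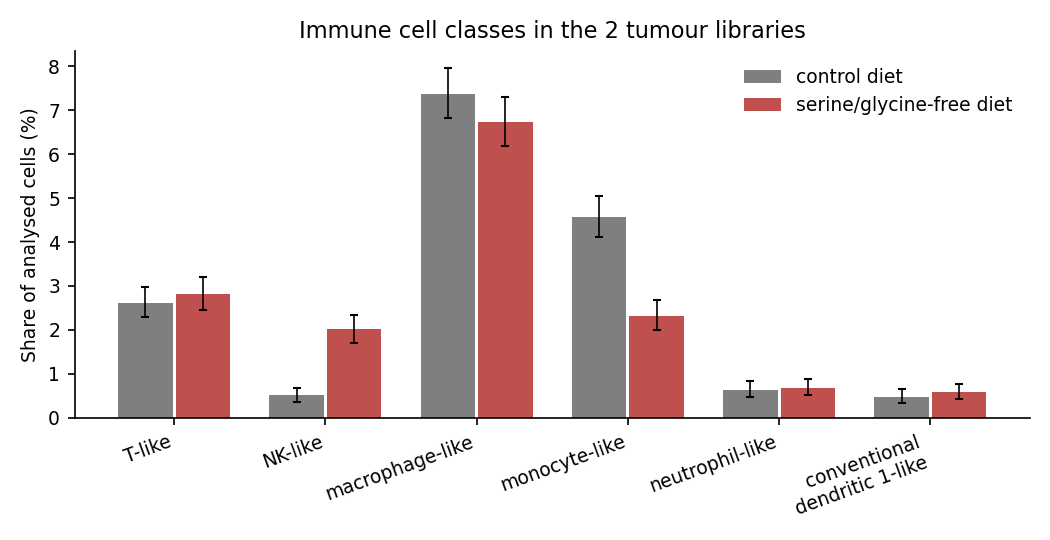
Shares of analysed cells (%, linear axis from 0) in 6 immune classes of the control diet library (grey) and the serine/glycine-free diet library (red); bars are the single library's share and error bars its 95% Clopper-Pearson interval. NK-like cells stood at 2.01% against 0.508% and monocyte-like cells at 2.33% against 4.56%, while the T-like shares of 2.81% and 2.62% had overlapping intervals.

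Within the T-like cells, CD8 T-like cells, the killer T cell class, formed 69.4% (62.9 to 75.4) in the serine/glycine-free library and 37.0% (30.6 to 43.9) in the control library, 154 and 80 cells, with a ratio of 1.87 (1.42 to 2.49). Regulatory T-like cells, named from Foxp3, counted 26 in each library, 11.7% and 12.0%. No sub-cluster met the naming rule for other CD4 T cells, which bounds no share of such cells: a stricter cell filter named a CD4 sub-cluster of 20 serine/glycine-free and 39 control cells. T-like cells without a subset name formed 18.9% and 50.9%. Different clusters held most of the T-like cells, and different sub-clusters most of the CD8 T-like cells, in the 2 libraries. Cluster 14, whose leading genes include the haemoglobin gene Hbb-bs, held 202 of the 216 control T-like cells, and cluster 19, led by Nrgn and Pdcd1, held 124 of the 222 serine/glycine-free ones. Among CD8 T-like cells, sub-cluster 2 held 59 of 80 control cells and sub-cluster 1 held 104 of 154 serine/glycine-free cells. When cells with a TRB contig were called from their own Cd8a, Cd8b1 and Cd4 UMIs, whatever their cluster, 83.8% (78.0 to 88.7) of 198 called serine/glycine-free cells and 55.2% (46.0 to 64.1) of 125 called control cells were CD8, and the remaining 32 and 56 were CD4; this call was added after the data were seen. These UMIs allowed no call for 45 of 243 serine/glycine-free and 117 of 242 control cells with a TRB contig. Depth was not matched for this call, and T-like cells had a median of 4624 and 2146 UMIs in that order. The CD8 ratio among T-like cells was 1.0 at a resolution of 0.5, where few control cells kept the T-like name. It was also lower under the strict cell filter.

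Receptor contigs of any kind were recovered about equally from T-like cells of both diets, while pairs were recovered less often in the control library. A productive contig was found in 93.7% (89.6 to 96.5) of serine/glycine-free and 92.1% (87.7 to 95.3) of control T-like cells, and a TRA and TRB pair in 86.0% and 76.4%. As background, 1 of 532 and 2 of 609 macrophage-like cells, 0.188% and 0.328%, carried a contig. NK-like cells carried one in 13.2% (21 of 159) and 57.1% (24 of 42), and with a doublet score of 0.25 or less in 10.2% (14 of 137) and 55.9% (19 of 34). Under the strict cell filter 1 of 105 and 5 of 18 did. T cells inside the NK-like cluster and doublets that hold a T cell were not separated cell by cell.

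The next comparison asked how far T cell clones had expanded. In the serine/glycine-free library, 59.7% (52.4 to 66.7) of the 191 T-like cells with a receptor pair belonged to clonotypes of at least 2 cells. The share in the control library was 17.6% (12.1 to 24.3) of 165 cells. The 191 cells formed 88 clonotypes and the 165 cells formed 149. Drawing 165 cells at random from the serine/glycine-free library gave an expanded share of 59.2% on average. The largest clonotype held 36 cells, 18.8% (13.6 to 25.1), against 4 cells, 2.42% (0.664 to 6.09), in the control library. Without the largest clonotype of each library, the expanded shares were 50.3% and 15.5%, and 43.2% and 14.8% by the deposited clonotype numbers, which join cells with and without a further TRA chain.

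Expansion sat in the CD8 T-like cells of the serine/glycine-free library, where 111 of 139 cells with a pair, 79.9% (72.2 to 86.2), were in expanded clonotypes, against 13 of 66, 19.7% (10.9 to 31.3), in the control library. Among regulatory T-like cells 3 of 24 and 1 of 18 were expanded. Among T-like cells without a subset name 0 of 28 serine/glycine-free cells, which allows up to 10.7% by the 3 counts used for a count of 0 (exact upper bound 12.3%), and 15 of 81 control cells, 18.5%, were expanded. The largest deposited clonotype of the serine/glycine-free library, with the TRB chain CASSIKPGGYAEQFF of TRBV19 and TRBJ2-1, held 62 barcodes, 57 of them T-like and all 57 CD8 T-like; whatever the deposited clonotype, that chain was found in 64 barcodes. All 62 also carried the TRA chain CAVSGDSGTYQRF, and 38 a further TRA chain, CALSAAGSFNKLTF. Detection of that further chain split the clone into the paired clonotypes of 36 and 21 cells, and counting by TRB alone gave it 27.8% of T-like cells with a TRB. The next deposited clonotypes were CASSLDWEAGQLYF with TRBV10 in 20 barcodes and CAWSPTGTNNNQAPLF with TRBV31 in 15. The largest control one, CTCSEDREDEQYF with TRBV1, held 5 barcodes.

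**Figure D2:**
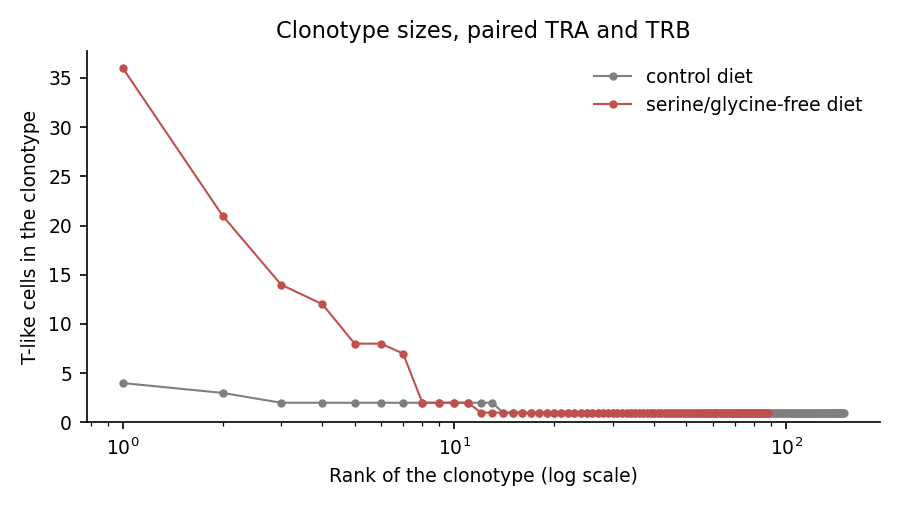
Number of T-like cells (linear axis) in each clonotype, defined by paired TRA and TRB sequences, against its rank (log axis), for the control diet library (grey) and the serine/glycine-free diet library (red); each point is 1 clonotype and there are no error bars. The serine/glycine-free library had clonotypes of 36, 21, 14 and 12 cells, and the largest control clonotype had 4.

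Few sequences were shared between the libraries. Of the TRB amino-acid sequences, 216 in the control and 110 in the serine/glycine-free library, 1 occurred in both (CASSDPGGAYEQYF, 1 cell each). Of the TRA sequences 3 did (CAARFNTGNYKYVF, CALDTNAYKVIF and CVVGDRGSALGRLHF), in 4 of 230 control and 4 of 229 serine/glycine-free cells; at the nucleotide level 0 were shared in either chain. The invariant chain of NKT cells, TRAV11 with TRAJ18, was found in 2 cells of each library. Counted by clonotype, the leading TRBV genes were TRBV31 (11.4%), TRBV19 (10.8%) and, tied at 9.66%, TRBV1, TRBV13-1 and TRBV13-3 in the control library, and TRBV19 (12.5%), TRBV13-3 (11.5%) and TRBV31 (10.4%, level with TRBV5) in the serine/glycine-free library. The largest differences were TRBV20, TRBV29 and TRBV2 on the higher side (7.29% against 3.98%, 6.25% against 2.84% and 6.25% against 2.27%) and TRBV1, TRBV13-1 and TRBV17 on the lower side (4.17% against 9.66% for the first and the second, 1.04% against 3.98% for the third). Every one of these 6 ratios had an interval that held 1, so by clonotype no difference in the use of these genes was detectable at this depth. Counted by cells, which lets large clones weigh more, TRBV19, the gene of the largest clone, was at 33.2% against 11.8%, ratio 2.82 (1.72 to 4.79). TRBV1 (1.95% against 11.2%, ratio 0.174, 0.0434 to 0.515), TRBV13-1 (2.44% against 10.2%, ratio 0.240, 0.0701 to 0.665) and TRBV17 (ratio 0.114, 0.00257 to 0.850) had intervals below 1. A large clone lowers the shares of the other genes, and these intervals count cells of the same clone as independent.

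Within each library, cells of expanded CD8 clonotypes were set against CD8 cells with a unique receptor. In the serine/glycine-free library (111 and 28 cells), expanded cells had more Prf1, the pore-forming perforin, with a ratio of 4.01 (2.81 to 5.92). They also had more of the inhibitory receptor gene Pdcd1 (1.81, 1.47 to 2.25) and of Tox, a transcription factor of exhausted T cells (1.77, 1.27 to 2.52), and less Ccr7, the lymph node homing receptor (0.263, 0.185 to 0.375). Tcf7, a factor of naive and memory T cells, had 2 counts in expanded and 11 in unique cells, a ratio of 0.0357 (0.00385 to 0.164). The exhaustion list had a median log2 ratio of 0.31 (0.07 to 0.58) and the naive and memory-like list one of -1.23 (-1.66 to -0.50). The proliferation median was 0.05 (-0.16 to 0.21), with Mki67 at a ratio of 0.802 (0.600 to 1.09) and Top2a at 0.692 (0.519 to 0.935). The unique cells also held RNA of other cell types: expanded over unique, Cd4 had a ratio of 0.216 (0.0833 to 0.567), Foxp3 had 1 count against 6, and the MHC class II list had a median of -3.09 (-3.42 to -2.56). Expanded and unique cells also lay in different sub-clusters: 81, 28 and 2 expanded and 12, 5 and 11 unique cells in sub-clusters 1, 4 and 2. The 111 expanded cells included the paired clonotypes of 36 and 21 cells that belong to the largest clone. The intervals count cells of the same clone as independent, and the contrast was not run without that clone. Contrasts within a sub-cluster were added after the data were seen. Within sub-cluster 1, Prf1 had a ratio of 2.92 (1.94 to 4.60), Pdcd1 one of 1.96 (1.43 to 2.77), Tox one of 1.95 (1.17 to 3.47) and Ccr7 one of 0.269 (0.169 to 0.437), and Tcf7 had 0 counts against 4; Cd4 (0.0697, 0.0113 to 0.326) and MHC class II (-3.98) were lower there too. Within sub-cluster 4, Prf1 (3.74, 1.77 to 9.47) and Ccr7 (0.135, 0.0748 to 0.240) kept their direction, while Pdcd1 (1.17, 0.862 to 1.61) and Tox (1.04, 0.665 to 1.70) had intervals that held 1. In the control library (13 and 53 cells), Prf1 had a ratio of 2.70 (1.41 to 5.06), Mki67 one of 2.69 (1.34 to 5.24), Top2a one of 3.79 (1.36 to 10.4) and Pdcd1 one of 0.914 (0.486 to 1.61), with list medians of 0.72 (0.27 to 1.06) for exhaustion, -0.75 (-1.77 to 0.01) for naive and memory-like and 0.99 (0.68 to 1.45) for proliferation. Requiring 3 cells for an expanded clonotype left 2 expanded control cells, with which the exhaustion median was -4.71, the naive and memory-like median 1.64 and the proliferation median -4.50. Within sub-cluster 2 (9 and 38 control cells) Prf1 had a ratio of 3.65 (0.567 to 18.8), and the list medians were 0.50 (-0.78 to 0.94) for exhaustion, -0.02 (-1.79 to 0.82) for naive and memory-like and 0.95 (-0.03 to 1.37) for proliferation; the interval of the ratio held 1 and those of the medians held 0.

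In T-like cells as a whole (222 and 216 cells, 1315156 and 594938 UMIs, median 4624 and 2146 UMIs per cell), genes of exhausted and of dividing T cells were higher in the serine/glycine-free library, and genes of naive T cells and of the interferon response were lower. Of 14 measured exhaustion genes 13 were higher, with a median log2 ratio of 1.20 (0.90 to 1.31), above all 10000 random lists matched on size and expression. Pdcd1 was at 817 against 208 CPM (UMIs per library and class scaled to a common total), a ratio of 3.92 (3.25 to 4.76), Nr4a2 at 414 against 121 and Tox at 351 against 124. Of 18 proliferation genes 17 were higher (median 1.17): Ube2c stood at 287 against 31.9 CPM, Tpx2 at 92.0 against 16.8 and Cenpf at 122 against 25.2. Of 11 naive and memory-like genes 9 were lower (median -1.06), among them Tcf7 (24.3 against 136 CPM), S1pr1 (11.4 against 60.5) and Lef1 (20.5 against 75.6). All 13 type I interferon genes were lower, with a median of -1.59, such as Ifit3 (31.2 against 182), Usp18 (19.01 against 101) and Cmpk2 (6.84 against 72.3).

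Of 18 interferon-gamma response genes 16 were lower in T-like cells (median -0.58), including the guanylate-binding proteins Gbp2 (79.8 against 282 CPM) and Gbp4 (98.8 against 274), and 11 of 12 genes of MHC class I presentation were lower (median -0.24). The cytotoxic list was split, 8 higher and 7 lower (median 0.20). Its members Prf1 (571 against 82.4 CPM, ratio 6.93, 5.19 to 9.46) and Gzma (18.2 against 234, ratio 0.0781, 0.0484 to 0.121) lay at opposite ends, and Gzmb was at 888 against 1817. Of 8 regulatory T genes 6 were lower (median -0.51), with Il10 at 19.01 against 89.1 CPM, Foxp3 at 59.3 against 104 and the chemokine receptor gene Ccr8 as an exception at 150 against 33.6. Regulatory T-like cells supplied 79292 of 1315156 serine/glycine-free and 61791 of 594938 control UMIs. They thus weighed less in the serine/glycine-free sum, and the lower values were not separated from this. Glycolysis (median 0.21, 10 of 14 higher, Tpi1 835 against 565 CPM) and serine, glycine and one-carbon genes (median 0.22, 10 of 14 higher, Gldc 47.9 against 8.40) lay inside the limits set for random lists, the first at percentile 96.9. The remaining genes with the largest ratios were Nrgn, Slc17a6, Serpinb6b, Cd74, Cenpa, Eno3 and Nrn1 on the higher side and Ecm1, Pmepa1, Slfn5, Tgtp1, Cd40lg and Ifit3b on the lower side. Nrgn and Pdcd1 lead cluster 19, which was rare in the control library. When T cells were defined by a TRB contig, the serine, glycine and one-carbon median was -0.22, the MHC class I median 0.05 and the chemokine median 0.081, against -0.56 in T-like clusters; a mean over cells gave a chemokine median of 0.057.

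Within CD8 T-like cells (154 and 80 cells, 1127455 and 308258 UMIs, median 6339 and 3266.5 UMIs per cell), the exhaustion, proliferation, naive and memory-like and interferon lists kept the direction of T-like cells. The cytotoxic median (-0.28 against 0.20 in T-like cells) and the regulatory T median (0.16 against -0.51) did not. Of 14 exhaustion genes 12 were higher in the serine/glycine-free library (median 1.06, 0.85 to 1.34), with Pdcd1 at 936 against 298 CPM, a ratio of 3.14 (2.53 to 3.92), Tox at 378 against 123, Tigit at 377 against 123 and Ctla4 at 378 against 149. Prf1 was at 665 against 149 CPM, a ratio of 4.46 (3.31 to 6.14), whereas Gzmb (891 against 2556), Gzma (21.3 against 412) and Gzmc (21.3 against 172) were lower, as were 9 of 15 cytotoxic genes (median -0.28, but 0.14 by a mean over cells and 0.13 in sub-cluster 2 alone). Ifng, the gene of interferon-gamma, was at 466 against 380 CPM, a ratio of 1.23 (1.0 to 1.51). All 13 type I interferon genes were lower (median -2.27, -2.74 to -1.87): Rsad2 was at 5.32 against 191 CPM, Ifit3 at 20.4 against 285 and Usp18 at 13.3 against 175. Of 18 interferon-gamma response genes 16 were lower (median -0.98), with Gbp2 at 39.9 against 295 and the chemokine gene Cxcl10 at 135 against 646. Of 10 naive and memory-like genes 8 were lower (median -1.53), such as Lef1 (9.76 against 64.9), with Ccr7 as an exception at 123 against 26.0. Of 18 proliferation genes 15 were higher (median 0.94), such as Top2a at 252 against 61.6.

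Further CD8 lists were lower for MHC class I presentation (median -0.35, 11 of 12, Tap2 157 against 276 CPM), T cell attracting chemokines (median -0.77, 4 of 5, Ccl5 569 against 2053) and inflammatory genes (median -0.69, 2 of 3, Tnf 175 against 285), and higher for dissociation stress genes (median 0.30, 11 of 16, Atf3 179 against 64.9) and for the 2 measured extracellular matrix genes, Fn1 and Tgfb1 (median 1.29). Directions turned for chemokines and inflammatory genes under a mean over cells (0.13 and 0.52) and in sub-cluster 2 alone (0.86 and 2.11), for inflammatory genes with all genes that had a count (0.14), and for MHC class I and dissociation stress in sub-cluster 2 alone (0.033 and -0.11). The glycolysis median was 0.16 (12 of 14 higher, Tpi1 873 against 535) and the serine, glycine and one-carbon median 0.05 (8 of 14 higher, Shmt2 55.9 against 107), both inside the limits set for random lists; the former was -0.0041 in sub-cluster 1 alone and -0.36 in sub-cluster 2 alone. Mt1, a metallothionein, had the largest ratio, 10.7 (5.14 to 27.0), followed among the highest by Eno3, Serpinb6b, Arl14ep and Slc17a6. Mt1 also stood at 6744 against 1797 CPM in unnamed non-immune cells. RNA of those cells, free or in doublets, was not told apart from Mt1 of CD8 T-like cells. Part of the CD8 contrasts followed the sub-clusters. Within sub-cluster 1 alone (104 and 18 cells) the exhaustion median was 0.58 and the type I interferon median -0.50, while the intervals of the naive (0.32, -0.36 to 1.16), proliferation (-0.35, -0.45 to 0.54) and interferon-gamma (0.17, -0.31 to 0.41) medians held 0. Within sub-cluster 2 alone (16 and 59 cells) they were 0.08, -0.73, 0.26, -2.35 and -0.55 in that order, with intervals that held 0 for exhaustion (-0.39 to 0.63) and for naive and memory-like (-0.69 to 0.61). Pdcd1 had a ratio of 2.0 (1.45 to 2.83) in sub-cluster 1 and 1.06 (0.467 to 2.18) in sub-cluster 2, and Prf1 one of 3.37 (2.18 to 5.48) and 1.39 (0.237 to 5.78). In sub-cluster 4 (34 and only 3 control cells) Prf1 had a ratio of 0.618 (0.374 to 1.09), Pdcd1 one of 1.47 (0.903 to 2.54), and the medians were 0.10 (-0.41 to 0.63) for exhaustion and 0.15 (-0.80 to 1.31) for type I interferon. TMM scaling moved the median of all genes by 0.10 in this class.

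**Figure D3:**
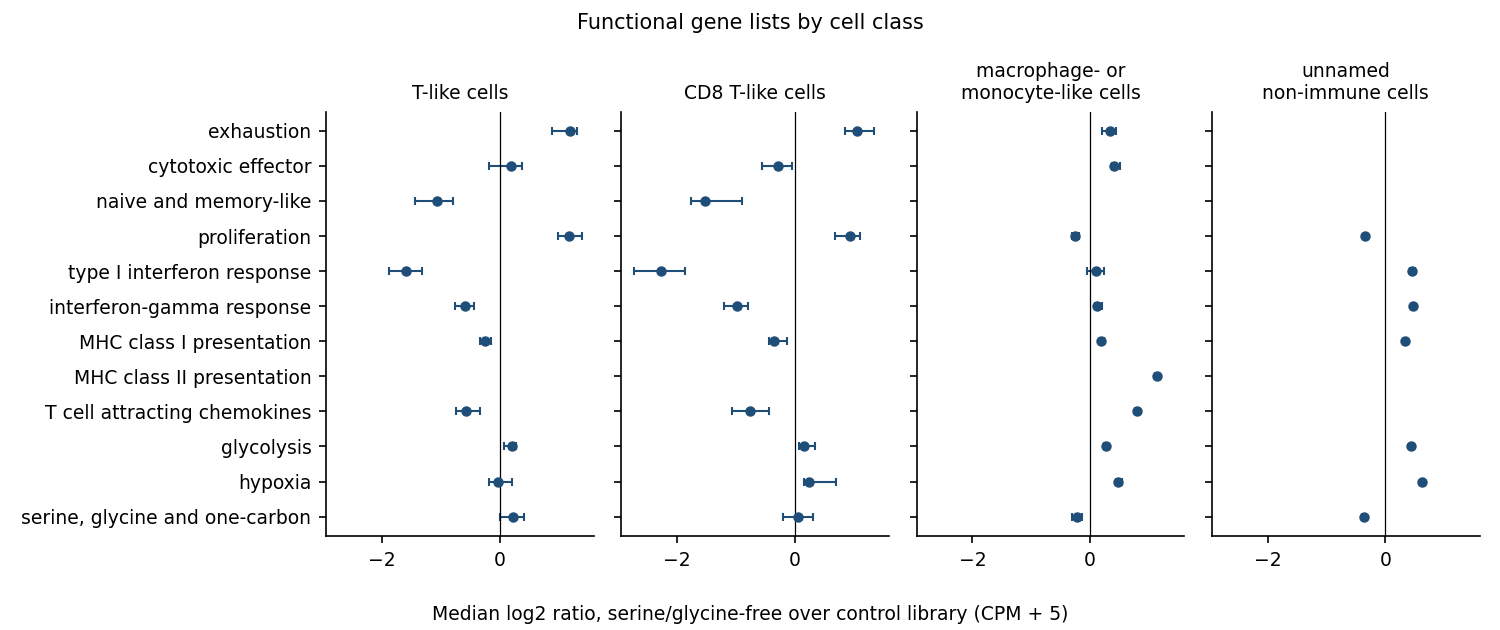
Median log2 ratio of CPM plus 5, serine/glycine-free over control library, for 12 gene lists in 4 cell classes; points are list medians, error bars their 95% counting intervals, and lists with fewer than 5 measured members have no point. The type I interferon list lay at -1.59 and -2.27 in T-like and CD8 T-like cells and at 0.45 in unnamed non-immune cells, and MHC class II reached 1.13 in macrophage- or monocyte-like cells.

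In macrophage- or monocyte-like cells (716 and 986 cells, 7518911 and 8449031 UMIs), antigen presentation and chemokine genes were higher in the serine/glycine-free library, and genes of alternatively activated macrophages were lower. All 7 MHC class II genes were higher, with a median log2 ratio of 1.13 (1.10 to 1.15): H2-Eb1 was at 2738 against 1042 CPM, H2-Aa at 3479 against 1558 and Cd74 at 9884 against 4434. The list median was 1.91 in macrophage-like and 0.50 in monocyte-like cells taken apart. Of 7 T cell attracting chemokines 6 were higher (median 0.79), among them Ccl5 (543 against 109, ratio 4.98, 4.63 to 5.35), Cxcl9 (863 against 435), Ccl8 (4025 against 2113) and Ccl4 (3084 against 1782). Cxcl13, which attracts B cells, was at 101 against 11.6, the adhesion gene Vcam1 at 125 against 20.4 and the interferon gene Ifnb1 at 85.5 against 17.9.

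Of 12 genes of alternative activation 10 were lower (median -0.39), including Retnla (3.99 against 185 CPM, ratio 0.0216, 0.0145 to 0.031), Spp1 (457 against 1319.7), Ccl24 (20.7 against 65.0) and Lyve1 (9.97 against 31.6). Retnla is among the leading genes of the monocyte-like cluster, and a small macrophage-like cluster led by Wfdc17 and Retnla held 36 control cells and 6 serine/glycine-free cells. Monocyte genes Ly6c2 (273 against 568) and Ccr2 (90.6 against 190) were lower along with the monocyte-like share. Hypoxia genes were higher in 9 of 10 cases (median 0.47, Vegfa 63.6 against 25.8, Ndrg1 313 against 168), glycolysis genes in 13 of 14 (median 0.26, Slc2a1 210.0 against 144), interferon-gamma genes in 15 of 19 (median 0.12, Psmb9 483 against 348), MHC class I genes in 11 of 11 (median 0.19, B2m 2728 against 2274) and inflammatory genes in 8 of 11 (median 0.34, Cxcl1 114 against 64.1, Cxcl3 7.98 against 61.5). The type I interferon list was split, 8 higher and 7 lower (median 0.10, Ifih1 226 against 108, Cmpk2 23.4 against 37.0). In macrophage-like and monocyte-like cells taken apart, the inflammatory medians were 0.52 (9 of 10 higher) and -0.06 (4 of 12), the type I interferon medians 0.19 (9 of 14) and -0.11 (7 of 15), the exhaustion medians 0.34 (5 of 5) and -0.05 (3 of 7), the interferon-gamma medians 0.27 (16 of 19) and 0.16 (15 of 20), and the alternative activation medians -0.51 (1 of 13) and -0.22 (5 of 11). Dissociation stress genes, a sign of handling, went the same way as the inflammatory ones, with medians of 0.31 (15 of 16 higher) and -0.33 (2 of 16). Proliferation genes were lower in 15 of 18 cases (median -0.25, Ccnb2 43.6 against 73.6), serine, glycine and one-carbon genes in 8 of 10 (median -0.23, Psat1 37.0 against 47.9; at percentile 3.69, inside the limits set for random lists) and extracellular matrix genes in 4 of 5 (median -0.50, Fn1 88.7 against 279). Taken apart, the proliferation medians were -0.36 (1 of 18 higher) in macrophage-like and 0.21 (-0.02 to 0.43, 2 of 2 measured genes higher) in monocyte-like cells. The few measured members of the cytotoxic list (5 of 5 higher, median 0.40) were mainly the chemokine and cytokine genes Ccl3, Ccl4 and Tnf, and those of the exhaustion list (5 of 6, median 0.34) included Cd38 (47.1 against 16.8) and Entpd1 (92.0 against 76.2). Other genes with the largest ratios were Ly6i, Jdp2, Serpina3g and Hspa1b on the higher side and Fcrls, Fcna, Lsp1, Cbr2 and Gpr183 on the lower side.

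The unnamed non-immune cells (6459 and 6576 cells, 140966130 and 145757632 UMIs) took the place of a tumour cell class. In the serine/glycine-free library all 12 glycolysis genes were higher (median log2 ratio 0.44, 0.42 to 0.46), with the glucose transporter Slc2a1 at 133 against 84.7 CPM, Pgk1 at 2359 against 1405 and Aldoa at 1799 against 1172. All 12 hypoxia genes were higher (median 0.62), such as Car9 (45.8 against 15.9), Ndrg1 (370.2 against 177) and Bnip3 (366 against 196). Serine, glycine and one-carbon genes were lower in 14 of 15 cases (median -0.37, -0.40 to -0.35): Shmt2, the mitochondrial enzyme that interconverts serine and glycine, was at 125 against 182, Psph, the last enzyme of serine synthesis, at 63.9 against 92.3 and Tyms at 73.8 against 103. Interferon genes stood higher here, opposite to the T-like cells: 15 of 15 of the interferon-gamma list (median 0.47, Cxcl10 240 against 99.4, Gbp2 212 against 123) and 11 of 11 of the type I list (median 0.45, Ifih1 74.2 against 34.6, Ifit1 75.6 against 35.8). All 10 MHC class I genes were higher (median 0.34, B2m 1744 against 1267) and all 18 proliferation genes lower (median -0.34, Rrm2 95.2 against 155, Ccna2 78.2 against 114).

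The largest ratios in these cells belonged to Mt2 (4.17, 4.13 to 4.2), Mt1 (3.75, 3.74 to 3.77), Cebpd (3.70), Tsc22d3 (3.75), Ccn2 (3.89), Ddit4 (3.30), Sgk1 (3.11) and Fkbp5 (3.10); several of these are known targets of the glucocorticoid receptor. The lowest were Cyb5r1 (0.549), Slit2 (0.584), Dnph1 (0.592), Eno3 (0.610), Ppic (0.612), Igfbp6 (0.613), Rrm2 and Timp1 (0.624). Dissociation stress genes were higher in 13 of 14 cases (median 0.55, Dusp1 905 against 365, Zfp36 530.0 against 252), and lactate handling genes in 5 of 7 (median 0.23, Ldha 2792 against 2375). The 3 measured exhaustion genes, Tnfrsf9, Bhlhe40 and Nr4a2, had a median of 0.59, and no cytotoxic gene reached the expression minimum. Iron and glutathione genes were lower in 7 of 11 cases (median -0.22, Txnrd1 36.2 against 54.4). Within the 12 clusters of at least 100 cells per library, the medians ran from -0.46 to -0.05 for serine, glycine and one-carbon genes, from 0.15 to 0.65 for the interferon-gamma list, from -0.14 to 0.54 for the type I list (positive in 10, negative in 2), from -0.05 to 0.44 for glycolysis and from 0.03 to 0.60 for hypoxia. The lowest type I median, -0.14 (-0.21 to -0.057), was that of cluster 11, which interferon genes such as Ifit3 lead. The cluster led by the hypoxia genes Ndrg1 and Car9 held 1164 serine/glycine-free and 421 control cells, and its own hypoxia median was 0.03. Proliferation was positive in 4 of the 12 clusters and negative in 8 (-0.21 to 0.17). The pooled medians of glycolysis (0.44) and hypoxia (0.62) lay at the upper end of the cluster ranges, and that of proliferation (-0.34) lay below its range. Part of these pooled values thus lay in which clusters the cells came from.

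The series title names PD-L1, the ligand of the inhibitory receptor PD-1, and Cd274 is its gene (ENSMUSG00000016496, GRCm38 chromosome 19, 29362107 to 29388095). Cd274 RNA was higher in the serine/glycine-free library in macrophage-like cells, 138 against 62.8 CPM, a ratio of 2.2 (1.96 to 2.48), and in monocyte-like cells, 359 against 251, a ratio of 1.43 (1.25 to 1.64). In unnamed non-immune cells it was at 25.5 against 13.2 CPM, a ratio of 1.93 (1.83 to 2.05). Regulatory T-like cells (580.1 against 162, ratio 3.58, 1.78 to 7.97) and neutrophil-like cells (1689 against 904, ratio 1.87, 1.28 to 2.78) had more as well. It was lower in CD8 T-like cells, 87.8 against 195, a ratio of 0.451 (0.324 to 0.632), and in conventional dendritic 1-like cells, 80.2 against 311, a ratio of 0.258 (0.178 to 0.369). The cluster labels of the latter class (46 and 39 cells) were unstable, and its Cd274 ratio was not repeated under an alternative. The wider list of checkpoint ligands had medians near 0: 0.11 in T-like cells (3 of 6 higher), -0.18 in CD8 T-like cells (3 of 7), 0.09 in macrophage- or monocyte-like cells (2 of 4) and -0.12 in unnamed non-immune cells (0 of 2). The sign turned in every class under an alternative: with all genes that had a count the medians were -0.14, 0.04 and 0.0022 in the first, the second and the last class, and a mean over cells gave -0.023 in the third.

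Shares of cells with a Cd274 UMI were also compared after thinning each cell to 1000 UMIs. In macrophage-like cells the thinned share was 9.79% against 5.79% and the unthinned share 54.3% against 31.2%, with median depths of 11292 and 10133 UMIs and 1 and 4 cells left out. In unnamed non-immune cells the thinned share was 3.01% against 1.38% and the unthinned share 22.2% against 15.6% (medians 19349 and 21034.5, 14 and 43 cells left out). In CD8 T-like cells it was 9.27% against 18.4% thinned and 40.9% against 36.2% unthinned (medians 6339 and 3266.5, 3 and 4 cells left out). No class was known to lack Cd274, so its free RNA was not measured, and the low values of the unnamed non-immune cells in both libraries were not separated from it. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which encodes PD-1, was found in 51.0% against 15.8% of thinned CD8 T-like cells and 84.4% against 36.2% of unthinned ones. In macrophage-like cells, which should lack it, the thinned shares were 0.188% (1 of 531) and 0 of 605 cells, which allows up to 0.496% by 3 counts (exact upper bound 0.608%).

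**Figure D4:**
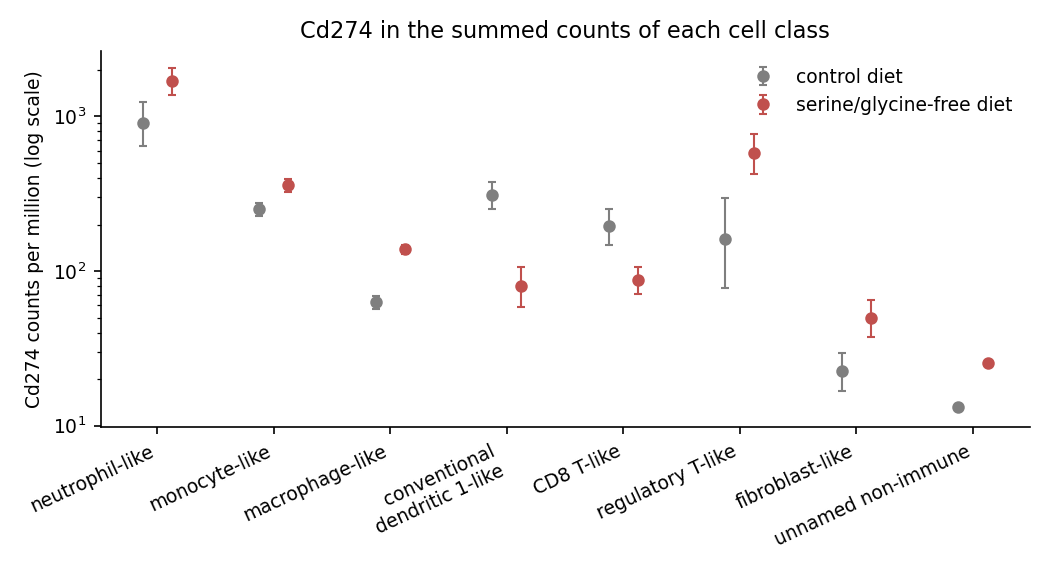
Cd274 in CPM (log axis) of the summed UMIs of 8 cell classes, for the control diet library (grey) and the serine/glycine-free diet library (red); points are 1 library each and error bars its exact 95% Poisson interval. The red point lies above the grey one in macrophage-like (138 against 62.8) and unnamed non-immune cells (25.5 against 13.2) and below it in CD8 T-like (87.8 against 195) and conventional dendritic 1-like cells (80.2 against 311).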

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

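Of the tests below, those on the number of cells, free receptor RNA, animals, doublets and T cells in the NK-like cluster were chosen only after the result was seen; those on similar barcodes, depth of the cells, clusters, heat-shock genes and the second gene list were chosen before.

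T cell receptor contigs lay in cells outside the T-like classes. They were found in 42 of 13035 unnamed non-immune cells, 0.322% (0.232 to 0.435), a share at the background of macrophage-like cells (0.188% and 0.328% in the serine/glycine-free and the control library); these cells had a median of 31980.5 UMIs and a mean doublet score of 0.164, against 20211 UMIs and 0.0553 in cells without a contig. They were also found in 45 of 201 NK-like cells, 22.4% (16.8 to 28.8), above that background, with a mean doublet score of 0.163 against 0.0674.

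The expanded clonotypes of the serine/glycine-free library stand out, with 59.7% of T-like cells with a pair against 17.6% in the control library. With equal numbers of cells drawn, the lowest 2.5% point of the expanded share was 56.4%, above the control upper bound of 24.3%. Each draw kept 165 of the 191 cells, so the share could not fall that far whatever cells were drawn. The draws are therefore no test of the larger number of cells. For 1 cell counted under several similar barcodes, 0 of the 2016 barcode pairs among the 64 barcodes with the dominant TRB chain were within a distance of 2, and for free receptor RNA of 1 clone in other droplets, 100% (94.4 to 100) of these 64 barcodes held a Cd3 UMI while 0 of 716 macrophage- or monocyte-like cells carried it. A difference between animals apart from the diet cannot be told apart from a diet effect with libraries per group at 1, since each tumour makes its own clones. A response of CD8 cells to the tumour that was larger under the serine/glycine-free diet may be 1 reading, which only more animals can test.

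The NK-like share was 3.95 times as high in the serine/glycine-free library. Without cells of a doublet score over 0.25 the ratio was 3.71 (2.52 to 5.60), which argues against doublets. Among NK-like cells without any receptor contig it was 8.0 (4.88 to 13.9; 138 and 18 cells), which argues against T cells in the cluster. After thinning, 83 of 7836 serine/glycine-free and 12 of 8116 control cells had an Ncr1 UMI, a ratio of 7.16 (3.89 to 14.4), which argues against cell depth. The remaining candidate explanations, the diet and differences between animals or tumour pieces, were not tested, because each diet had 1 library.

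Genes known as glucocorticoid receptor targets (Mt1, Mt2, Cebpd, Tsc22d3, Ddit4, Sgk1 and Fkbp5), picked because they led the unnamed non-immune comparison, had a median log2 ratio of 1.84 there. Within the 12 larger clusters the lowest median was 1.23 and the highest 2.09, which for these 7 genes argues against more cells of the clusters that express them. Heat-shock genes had a median of 0.35 (0.34 to 0.37) there, at percentile 99.9 of random lists. The median lay below the bound set in advance relative to 1.84, the outcome foreseen if stress of dissociation was not the source. The wider dissociation list stood at 0.55 (0.53 to 0.56), however, above that bound, and its members Dusp1 and Zfp36 respond to both. The 2 lists thus gave different answers, and stress of dissociation was left undecided in unnamed non-immune cells. A second list of glucocorticoid-induced genes, not looked at before, reached percentile 100 of random lists (median 0.85, 7 of 8 higher) here and 99.5 or more in macrophage-, fibroblast-, NK- and neutrophil-like cells, but 97.4 in regulatory T-like, 90.2 in T-like, 85.2 in monocyte-like, 48.4 in conventional dendritic 1-like and 33.4 in endothelial-like cells, while the first list was at 0.63 to 1.18 in macrophage-, monocyte-, fibroblast-, endothelial- and conventional dendritic 1-like cells and at 2.04 in NK-like cells (0.84 without cells of a doublet score over 0.25, which lowers the part of doublets with tumour cells), but at 0.06 in T-like, -0.09 in neutrophil-like and -1.28 in regulatory T-like cells. Within the 12 larger non-immune clusters the second list's median ran from 0.14 to 1.09, over 0.5 in 7 clusters and under 0.3 in 2. These values go with a glucocorticoid response in several, not all, cell classes of the serine/glycine-free tumour, a hypothesis found on the same data. Whether the diet or the handling of the animals would be behind it was not tested. Heat-shock medians were 0.30 in macrophage-like and 0.51 in fibroblast-like cells, against 1.05 and 1.18 for the first list, which did not meet the bound. Stress of dissociation was thus not argued against in those classes. In NK-, monocyte-, endothelial- and conventional dendritic 1-like cells heat-shock medians were 0.42, -0.06, 0.01 and -0.04. Their upper counting limits were 0.63, 0.06, 0.34 and 0.27, and the bound was met in monocyte-like cells only.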

How the results depend on the processing

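Alternatives to each step were chosen before the data were examined, except for those named here as added, which were chosen after seeing the data: leaving out cells with a doublet score over 0.25, adding the mixed macrophage cluster, leaving out the largest clone, CD8 calls from a cell's own UMIs, and each CD8 sub-cluster alone, also for expanded against unique cells. Of 173 values that answer a comparison under an alternative, 119 stayed within their counting interval, 51 moved outside it and 3 reversed. Of 531 other values, 384 stayed, 121 moved and 26 reversed. A value counted as reversed only where its sign turned and the main interval did not hold the value of no difference. Where the main interval held that value, a turned sign was counted among the stayed or the moved values. No paired analysis was possible because each diet had 1 library and the labels link no animals. Counts of genes beyond a fold were not run, as 1 library per group gives no test; list medians over all genes with a count took their place. Where no cause is given below, the cause was not tested.

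With TMM scaling the macrophage- or monocyte-like medians were 1.21 for MHC class II and 0.87 for chemokines, and the unnamed non-immune medians 0.50 for glycolysis, 0.68 for hypoxia, -0.31 for serine, glycine and one-carbon genes and 0.53 for interferon-gamma. Median-of-ratios factors gave 1.21 and 0.87, then 0.48, 0.66, -0.33 and 0.51. A pseudocount of 1 gave 0.46, 0.64, -0.40 and 0.51 in unnamed non-immune cells. With all genes that had a count, MHC class II was at 1.07 and chemokines at 0.60 in macrophage- or monocyte-like cells, hypoxia at 0.58, one-carbon genes at -0.23 and checkpoint ligands at 0.0022 in unnamed non-immune cells, and inflammatory genes in CD8 T-like cells at 0.14. A mean over cells, which weights shallow cells more, gave 0.057 for T-like chemokines, 0.14 for CD8 cytotoxic genes, 0.13 for CD8 chemokines and 0.52 for CD8 inflammatory genes; it gave 0.81 for MHC class II, -0.023 for checkpoint ligands and 0.71 for chemokines in macrophage- or monocyte-like cells, and 0.40, 0.56, -0.49 and 0.57 for the lists of unnamed non-immune cells in the order above.

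T cells defined by a productive TRB had medians of 1.42 for exhaustion, -0.22 for one-carbon genes, 0.047 for MHC class I and 0.081 for chemokines. Without doublet removal, which put back only 2 control cells and so changed little but the cluster labels, MHC class II was at 1.03. With the added score limit it was at 0.97 and chemokines at 0.76, and with the mixed cluster added they were at 1.05 and 0.67, with checkpoint ligands at -0.00067. In sub-cluster 1 alone the CD8 medians were 0.58 for exhaustion, 0.32 for naive and memory-like, -0.35 for proliferation, -0.0041 for glycolysis, 0.17 for interferon-gamma and -0.50 for type I interferon. In sub-cluster 2 alone they were 0.079, 0.26, -2.35 and -0.36 for the first 4, then -0.73 for type I interferon, 0.13 for cytotoxic genes, 0.033 for MHC class I, 0.86 for chemokines, 2.11 for inflammatory genes and -0.11 for dissociation stress; only 16 serine/glycine-free cells were left. These settings show that part of the CD8 contrast lay in which sub-cluster the cells came from.

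With expanded clonotypes of at least 3 cells, only 2 expanded control cells were left, and the control medians were -4.71 for exhaustion, 1.64 for naive and memory-like and -4.50 for proliferation. Expanded over unique serine/glycine-free cells had medians of 0.26 for exhaustion and -1.35 for naive and memory-like in sub-cluster 1 alone but of -0.0087 and 0.10 in sub-cluster 4 alone, where 5 unique cells were left. The largest serine/glycine-free clonotype was 27.8% by TRB alone and 27.8% by the deposited clonotype numbers, because cells with and without the further TRA chain were then joined. At the nucleotide level 0 TRA and 0 TRB sequences were shared. With each library clustered alone the fibroblast-like ratio was 5.44, and 86.6% of control T-like cells had a contig, in a T-like cluster then led by Gzmf and Gzmd. At resolution 0.5 the T-like ratio was 9.96, the CD8 ratio 1.0, and contigs were found in 100% and 99.2% of T-like cells. At resolution 2.0 the fibroblast-like ratio was 1.24. The strict cell filter gave ratios of 1.43 for T-like, 5.99 for NK-like and 1.33 for CD8 T-like cells. By thinned shares the Cd274 ratio was 1.69 in macrophage-like and 2.18 in unnamed non-immune cells.

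No value was obtained for NK-like and conventional dendritic 1-like cells at resolution 0.5 and with each library alone, for neutrophil-like cells under the strict filter, and for regulatory and other T-like cells at resolution 0.5 (other T-like also with each library alone), because a library then had 0 cells with that name. Expanded and unique cells were not set apart within sub-cluster 2 of the serine/glycine-free library and sub-clusters 1 and 4 of the control library, where fewer than 5 expanded cells were left. Small cell numbers limit the depth of several classes, among them 80 CD8 T-like, 42 NK-like, 39 conventional dendritic 1-like and 26 regulatory T-like control cells and neutrophil-like cells with 43121 control UMIs.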

Other observations

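The values in this part were chosen only after they were seen, and no test was made on them. In unnamed non-immune cells 15 of 17 oxidative phosphorylation genes were lower in the serine/glycine-free library (median log2 ratio -0.17, percentile 7.49 of random lists). Of 14 genes of the Atf4 and integrated stress response, which answers amino acid shortage, 11 were lower as well (median -0.20, percentile 2.98). Both lists lay inside the limits set for random lists, and all measured genes of this class together had a median of -0.09. The same stress list was at 0.12 in T-like cells (9 of 12 higher) and 0.01 in macrophage- or monocyte-like cells (7 of 12 higher).

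Within the serine/glycine-free library, the 57 CD8 T-like cells of the largest clone were set against the 97 other CD8 T-like cells. Gzmb, which encodes granzyme B, was at 389 against 1198 CPM in the clone, a ratio of 0.325 (0.273 to 0.384). Pdcd1 was at 1166 against 795, a ratio of 1.47 (1.30 to 1.66), Prf1 had a ratio of 1.30 and Tox one of 1.25. Tcf7 had 0 counts in the clone and 14 in the other cells. The clone had 0 cells in sub-cluster 2, which gave the other cells 7 of these 14 counts, so the contrasts were repeated within sub-clusters 1 (43 and 61 cells) and 4 (14 and 20 cells) after the data were seen. There Gzmb had ratios of 0.303 (0.251 to 0.364) and 0.346 (0.210 to 0.547) and Pdcd1 of 1.35 (1.16 to 1.58) and 1.39 (1.13 to 1.71). Prf1 (1.03, 0.875 to 1.22) in the first and Tox in both (1.11, 0.859 to 1.42, and 1.24, 0.894 to 1.72) had intervals that held 1, and Tcf7 had 0 counts against 4 and 3. NK-like cells had 207 against 87.5 CPM of Ifng and 2236 against 3298 of Gzmb in the serine/glycine-free and the control library, but 13.2% and 57.1% of them carried a T cell receptor contig, so the cells compared differed in their content of T cells or of doublets with T cells. Regulatory T-like cells had 114 against 291 CPM of Pdcd1, a ratio of 0.390 (0.154 to 0.913; 26 cells each).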
